A study of Rattus norvegicus with 12 samples.

How the data were processed

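RNA of 12 samples was labelled with Cy3 and hybridised to 1-colour Illumina rat BeadChips, per the labels. The deposited table holds, for each probe and each array, a signal intensity that was not normalized and a detection p-value, per the file headers. The detection p-value is the scanner software's comparison of a probe with negative control probes, and its exact version is not given in the sources used here. The authors also deposited a table of processed intensity values on a linear scale, with array medians of 78.08 to 78.56, which look quantile normalized, but the method is not stated and the direction and centring needed no assumption because the values are single-colour levels. The not-normalized table was used for all results and the processed table as an alternative.

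Samples were grouped by their labels into untreated EC, EC with AS exosomes, EC with AS-Tspan8 exosomes, AS exosomes and AS-Tspan8 exosomes (2 arrays each) and AS cells and AS-Tspan8 cells (1 each). The treatment protocol also mentions growth factor treatment, and no sample analysed here carries that label. The 6 EC arrays and the 6 tumour cell and exosome arrays were processed as separate families. Intensities were corrected for background with normexp, using the detection p-values to infer the negative controls, quantile normalized with an offset of 16 and taken to log2 (limma 3.58.1 in R 4.3.3). Probes with a detection p-value under 0.01 on at least 2 arrays of the family were kept. Quantile normalization gives arrays of a family the same distribution, so it lifts undetected probes of exosome arrays, which have fewer detected probes than cell arrays. For this reason signals before normalization and other scalings are given beside the exosome results.

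Probe names came from the platform's annotation: 13793 probes had 1 gene symbol, 0 had several and 8730 were unnamed here. Of these, 13752 matched the reference gene table by gene ID and 0 symbols changed. For each of 13337 named genes the probe with the highest mean over the family's arrays was used, and unnamed probes were kept as features of their own, which gave 9025 features for EC (6772 named) and 9434 for tumour cells and exosomes (6741 named).

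Differences were tested with limma's moderated test (lmFit and eBayes) on group means and adjusted by the Benjamini-Hochberg method, with calls at adjusted p under 0.05. Exosomes were compared with cells with the line as an additive term, and the interaction was tested with 4 group means. The cell lines have 1 array each and are assumed to vary like the exosome arrays. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists tested in each comparison (23 in EC, 25 in tumour samples). At an estimated correlation camera works with the few residual degrees of freedom of each fit. Its high p-values therefore cannot tell correlation between members from too few arrays. Where no replicates existed, a list's median was placed among 10000 random lists, which draw genes independently. A group without detection is given as a bound, the mean of the brighter group over the dim group's floor, which is the higher, on each array, of the lowest detected signal and the probe's own, after normalization. The design, the lists, the alternatives and the rule for named genes were chosen before the data were examined, and tests added later are named as such where they appear or in this section. For gene lists the replicate block and the left-out arrays were added after the data were seen.

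Genes were named by rule: up to 8 with the highest and 8 with the lowest log2 difference among those past adjusted p 0.05, detected on every array of the higher group and with groups that did not overlap. Where none passed, the 4 of lowest unadjusted p per direction that met the other conditions were given as values. For each list described, up to 4 passing members with the largest differences or 2 of lowest p were named, for the cell lines the 8 highest and 8 lowest differences, and Tspan8 throughout. The genes behind the marker signals of EC were chosen after their values were seen.

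Replicate numbers come from the sample labels. Deviations of same-numbered EC arrays from their group means correlated at 0.495, 0.375 and 0.555 over genes, so the numbers were read as pairs in EC. The main EC fits left the number out, so their spread includes the difference between the numbers. The fit with the number as a block is given where it changes a call. Between AS and AS-Tspan8 exosomes the correlation was -0.412.

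The gene and list tests were tried on simulated data with 50 changed genes per size. Each gene was drawn as independent noise from its mean and spread on these arrays. Normalization and filtering were not simulated. In EC 2%, 46%, 100% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered with 14 false calls, between exosome kinds 0% at each size, and between exosomes and cells 0%, 0%, 64% and 82% with 8 false calls. Of 100 unchanged lists 0 were called, but the simulated genes were independent. This count therefore does not cover lists whose members vary together. Alternatives were no background correction, median scaling, all 12 arrays normalized or fitted together, no filter or detection on every array, the authors' processed values, a mean-variance trend with robust estimation, the replicate block, an added log2 limit of 1, and each array left out in turn. No scaling between arrays, the cell arrays normalized alone, a crossed pairing of exosome arrays, the counts on signals before normalization, lists restricted to features detected on all 4 exosome arrays, bounds under other scalings and a simulation of shared controls with the replicate pairing were added after seeing the data.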

Results

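Messenger RNA was measured on 12 rat expression arrays, 1 array per sample, in cells and exosomes of the BDX rat strain. Exosomes are small membrane vesicles that cells shed into their medium. They came from AS, a rat pancreatic carcinoma line, and from AS-Tspan8, a derivative of AS made to express the tetraspanin Tspan8, also called D6.1A or CO-029. Exosomes were collected from the serum-free medium of tumour cells starved for 36 hours. Aortic endothelial cells (EC below, as labelled) were starved overnight and then kept for 24 hours in medium with 2% serum, alone or with 10 µg/ml of exosomes. The groups were untreated EC, EC with AS exosomes, EC with AS-Tspan8 exosomes, AS exosomes and AS-Tspan8 exosomes with 2 arrays each, and AS cells and AS-Tspan8 cells with 1 array each.

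Summed signal per array was 10383650 to 12705558 in the EC samples, 13714493 in AS cells and 21955880 in AS-Tspan8 cells. It was 2696800 and 2924133 for AS exosomes and 2390577 and 2413936 for AS-Tspan8 exosomes. Probes detected numbered 8563 to 8923 on the EC arrays, 9269 in AS cells and 9389 in AS-Tspan8 cells. The AS exosome arrays detected 2535 and 3604 probes and the AS-Tspan8 exosome arrays 2342 and 2104. Replicate arrays correlated at 0.986, 0.985 and 0.972 in the EC groups, at 0.825 for AS exosomes and at 0.941 for AS-Tspan8 exosomes, across genes, which are not independent replicates. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The small number of arrays limits the precision of every value.

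Tspan8 itself separated the cell lines and was near background elsewhere. In AS-Tspan8 cells the Tspan8 probe read 2036 and was detected, and in AS cells it read 75.1 and was not, a level at least 4.36-fold lower after normalization. In exosomes the Tspan8 signal was 96.2 and 83.6 for AS and 87.6 and 89.2 for AS-Tspan8. Detection p was 0.0667 and 0.101 for AS exosomes and 0.0206 and 0.0267 for AS-Tspan8 exosomes, so none passed the limit of 0.01 and no fold was taken. The 6 EC arrays read 71.0 to 82.2 with no detection.

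**Figure D1:**
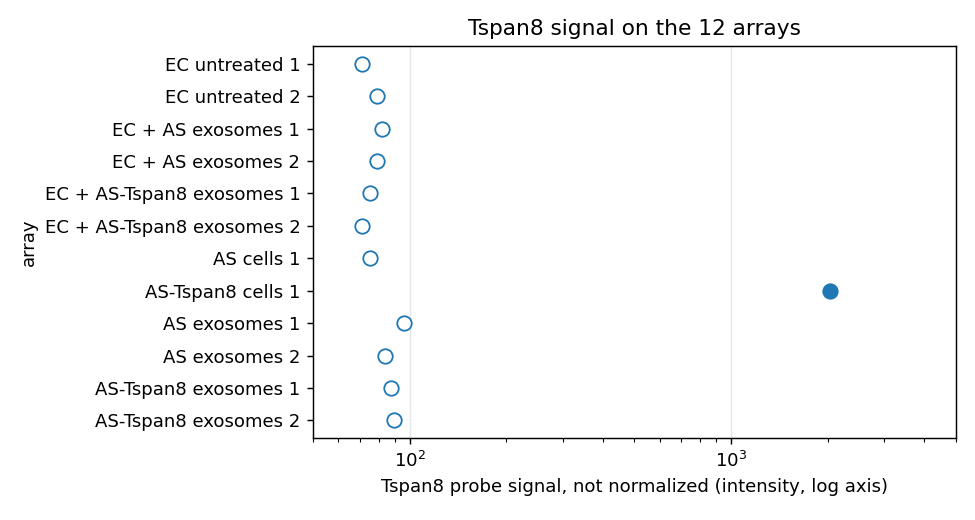
Signal of the Tspan8 probe before normalization on each of the 12 arrays, on a log axis. Filled points passed the detection limit and open points did not. The AS-Tspan8 cell array reads 2036, and no other array exceeds 96.2.

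Most markers of endothelial cells were not detected in the samples labelled EC, whereas most markers of fibroblasts were, at signals from near background to high. Of 18 endothelial marker genes named on the array, 3 were detected on all 6 EC arrays and 14 on none. The 14 included Cdh5 (VE-cadherin, the junctional adhesion protein of endothelium), Vwf (von Willebrand factor), Nos3 (endothelial nitric oxide synthase) and the receptor genes Tek and Tie1. Cdh5 read 53 to 73 and Vwf 55 to 75. The detected markers were Ramp2 (891 to 2365), Egfl7 (131 to 156) and Clec14a (125 to 180). Of 14 fibroblast marker genes, 12 were detected on all 6 arrays, with the proteoglycan gene Dcn at 22430 to 26660, the collagen gene Col1a2 at 14680 to 27370 and the growth factor receptor gene Pdgfra at 7028 to 13520. Other fibroblast markers read low, with Col1a1 at 118.7 to 310.2 and Mfap5 at 81.7 to 168.0, and Mfap4 (69.2 to 212.9) and Dpt (75.2 to 457.1) were detected on 5 arrays. Among all named genes 6061 of 13337 (45.4%) were detected on all 6 EC arrays. Fisher's exact test, two-sided, gave adjusted p = 0.0326 for the low endothelial share and 0.00774 for the high fibroblast share, adjusted over 6 cell type lists. Of 11 smooth muscle markers 4 were detected (adjusted p = 0.764), of 18 leukocyte markers 4 (0.0752), of 24 pancreatic epithelial and tumour markers 6 (0.0752), and of 22 exocrine and endocrine pancreas genes 0 (1.43e-05), all by the same exact test. These tests were chosen after seeing the data.

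**Figure D2:**
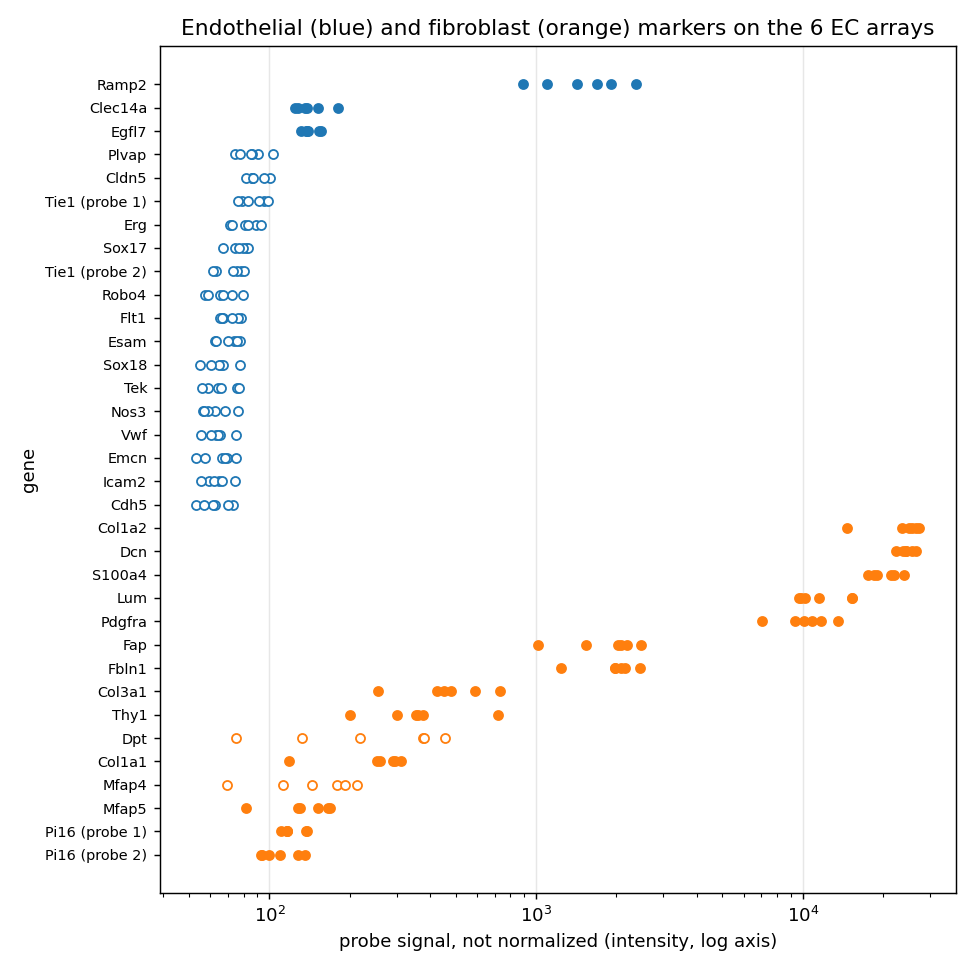
Signal before normalization of endothelial (blue) and fibroblast (orange) marker probes on the 6 EC arrays, on a log axis, 1 point per array. Filled points mark probes detected on all 6 arrays. Cdh5 and Vwf lie at 53 to 75, and Dcn at 22430 to 26660.

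Exposure of EC to exosomes of the parent line AS was compared with no exosomes. Genes of endothelial activation and NF-kB signalling, which encode adhesion molecules, cytokines and regulators of inflammation, rose as a list: 13 of 15 measured members were higher, with a median log2 difference of 0.23 (camera adjusted p = 0.000948; adjusted p = 0.906 with an estimated correlation). Nfkb2, an NF-kB subunit, differed by 0.35 ± 0.16 (log2 ± SE, n = 2 and 2) and the neutrophil chemokine Cxcl2 by 0.59 ± 0.37, and neither passed the test (limma adjusted p = 0.999 each). Without untreated replicate 2 the list's median relative to all genes was 0.07 and its adjusted p 0.504. Within replicate number 1 the median difference was 0.09, and within number 2 it was 0.31.

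With the replicate number as a block camera called 3 further lists in this comparison. Cell cycle genes then had a lower level (26 of 33 members lower, median -0.14, blocked adjusted p = 0.000341, unblocked 0.108). Cholesterol synthesis genes (14 of 16 higher, median 0.21) had blocked adjusted p = 0.00479 against 0.151, and glycolysis and hypoxia genes (19 of 25 higher, median 0.17) 0.0271 against 0.108. With an estimated correlation each of the 3 had an adjusted p = 0.906. Within replicate numbers 1 and 2 the medians were -0.15 and -0.155 for cell cycle, but -0.185 and 0.61 for cholesterol synthesis and -0.05 and 0.35 for glycolysis. The mitotic kinase Cdk1 differed by -0.45 ± 0.20 and the mitotic ubiquitin carrier Ube2c by -0.90 ± 0.42. Interferon response genes had a median of 0.07 (adjusted p = 0.248), with Ifit2 at 0.70 ± 0.28. Extracellular matrix and fibroblast marker lists had medians of -0.02 (0.903) and -0.04 (0.642).

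No single gene passed the test between EC with AS exosomes and untreated EC. Of 9025 features, 6772 of them named genes, 0 passed adjusted p 0.05 with limma, and 62 had an unadjusted p under 0.05 against 451 expected by chance. The block also gave 0, with 166 under 0.05. Of all features, 23.2% had groups that did not overlap. Among genes detected throughout the higher group and with groups apart, those of lowest p that were higher with AS exosomes were the semaphorin Sema4g (0.59 ± 0.17), the oxysterol-binding protein Osbpl7 (0.66 ± 0.20), Jrk (at least 1.25-fold) and the sorting protein Pacs1 (0.59 ± 0.19). Those lower were Spats2l (at least 1.23-fold), the kinase-like gene Cdkl3 (at least 1.25-fold), the homeobox gene Hoxc9 (-0.53 ± 0.18) and the galectin Lgals7 (-0.48 ± 0.16), all with adjusted p = 0.999. In simulated data on these arrays, 23 of 50 genes changed by 1 on the log2 scale were recovered and 1 of 50 changed by 0.5.

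Exosomes of AS-Tspan8 cells were compared with no exosomes in the same way. By camera, 3 lists rose in EC: endothelial activation and NF-kB targets (12 of 15 higher, median log2 difference 0.30, adjusted p = 0.000565), glycolysis and hypoxia genes (22 of 25 higher, 0.39, 0.00136) and genes of the unfolded protein and ATF4 stress response (17 of 23 higher, 0.18, 0.00424). As many fell: cell cycle genes (27 of 33 lower, -0.34, 0.0017), fibroblast markers (11 of 14 lower, -0.24, 0.00477) and extracellular matrix genes (20 of 26 lower, -0.19, 0.0366). With an estimated correlation all 6 had an adjusted p = 0.694, and fry gave 0.887 for each. The blocked fit gave adjusted p = 0.115 for the matrix list and 0.0126 for cholesterol synthesis genes (14 of 16 lower, median -0.22, unblocked 0.094; adjusted p = 0.76 with an estimated correlation).

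Members of these lists gave larger differences than with AS exosomes alone in some cases, none past the test (limma adjusted p = 1 each, n = 2 and 2). Cxcl2 differed by 0.82 ± 0.37 and Ptgs2, the inducible cyclooxygenase, by 0.88 ± 0.43. Angptl4, a hypoxia-induced regulator of lipoprotein lipase, differed by 0.76 ± 0.34, the haem-degrading enzyme Hmox1 by 0.83 ± 0.46 and asparagine synthetase Asns, an ATF4 target, by 0.74 ± 0.31. Cdk1 differed by -0.66 ± 0.20 and Ube2c by -0.98 ± 0.42. The surface glycoprotein Thy1 differed by -1.08 ± 0.35, the microfibril gene Mfap5 by -0.74 ± 0.38, osteopontin (Spp1) by -0.59 ± 0.22 and the collagen cross-linking enzyme Loxl1 by -0.42 ± 0.18.

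The calls of these lists depended on single arrays. Without untreated replicate 2 none of the 6 was called by camera: the medians relative to all genes were 0.19 for NF-kB targets (adjusted p = 0.148), 0.445 for glycolysis (0.0759), 0.12 for the stress response (0.593), 0.01 for cell cycle (0.823), -0.20 for fibroblast markers (0.148) and -0.02 for matrix (0.823). Without EC with AS-Tspan8 exosomes replicate 2 they were -0.17 for glycolysis (0.126), 0.12 for the stress response (0.155), 0.045 for fibroblast markers (0.928) and -0.055 for matrix (0.928). Without replicate 1 of that group the cell cycle median was -0.02. Within numbers 1 and 2, however, cell cycle genes differed by -0.17 and -0.36 (blocked camera adjusted p = 7.49e-08 at the preset correlation). Arrays 1 and 2 differed in this list by -0.81 in untreated EC and by -0.53 with AS-Tspan8 exosomes. Leaving out 1 array of a pair mixes that difference into the cell cycle median. Between arrays of number 1 glycolysis genes differed by -0.12 and between those of number 2 by 0.92, and fibroblast markers by -0.01 and -0.85. That replicate 2 array had the lowest of the 6 signals for Col1a2 (14680), Pdgfra (7028) and Fap (1017), where other EC arrays reached 27370, 13520 and 2475, but not for Dcn (25620), and its Lum signal (15350) was the highest.

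**Figure D3:**
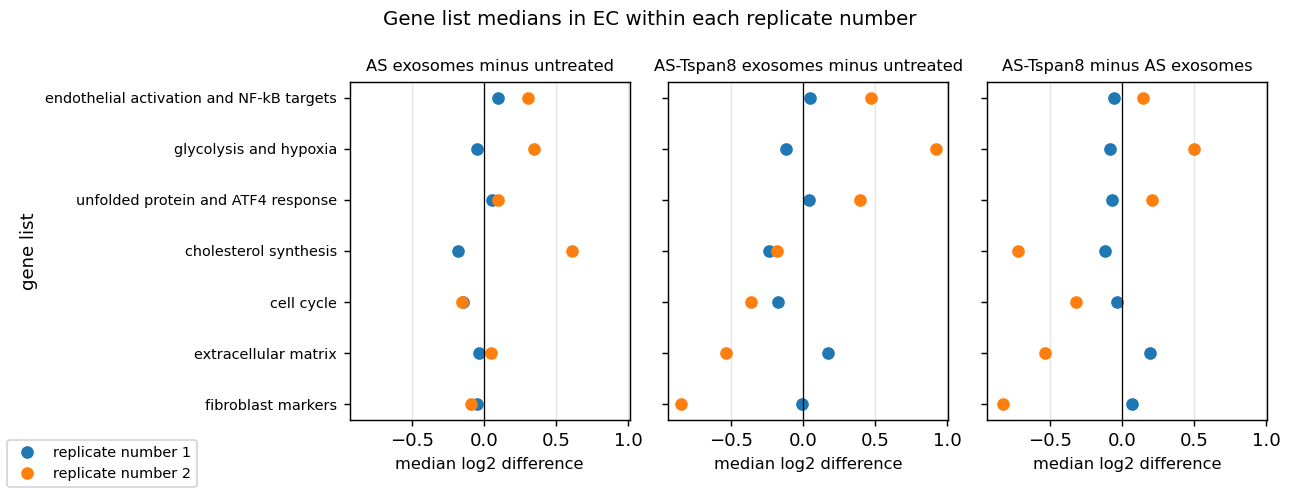
Median log2 difference over the members of 7 gene lists in EC, between arrays with the same replicate number (blue, number 1; orange, number 2). For AS-Tspan8 exosomes against untreated EC, glycolysis genes lie at -0.12 and 0.92 and fibroblast markers at -0.01 and -0.85.

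Again no single gene passed. With limma 0 of 9025 features had adjusted p under 0.05 for EC with AS-Tspan8 exosomes against untreated EC, and 117 had an unadjusted p under 0.05 against 451 expected; the block gave 0 and 483. Groups did not overlap in 25.1% of features. Without scaling between arrays the median of all genes was -0.13. The genes of lowest p that were higher were Cpt1a, which admits fatty acids into mitochondria (0.82 ± 0.19), Plekhn1 (0.75 ± 0.18), the amino acid transporter Slc7a7 (at least 1.26-fold) and Abtb2 (0.60 ± 0.17). Apolipoprotein E (Apoe) was lower by a log2 difference of -0.95 ± 0.23, and so were the receptor Ror1 (at least 1.46-fold), the growth factor Clec11a (at least 1.1-fold) and Cdk1. Adjusted p was 1 for each.

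The direct comparison of EC with AS-Tspan8 exosomes against EC with AS exosomes set exosomes of the 2 donor lines side by side. The lines also differed in transcripts other than Tspan8, given below, so a part of Tspan8 itself cannot be told apart. Cholesterol synthesis genes fell with AS-Tspan8 exosomes as a list, with all 16 members lower and a median of -0.38 (camera adjusted p = 6.88e-05, blocked 9.71e-10; adjusted p = 0.777 with an estimated correlation). Idi1, an isomerase of the isoprenoid pathway, differed by -0.73 ± 0.41 and Dhcr7, the last enzyme of cholesterol synthesis, by -0.67 ± 0.44. The list's median was -0.12 within replicate number 1 and -0.725 within number 2. Without EC with AS exosomes replicate 2 it was 0.23 relative to all genes (adjusted p = 0.192), and without EC with AS-Tspan8 exosomes replicate 1 it was -0.09 (0.644). The 2 untreated arrays differed from each other by -0.58 in the same list.

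Extracellular matrix genes (18 of 26 lower, median -0.17) and fibroblast markers (10 of 14 lower, median -0.32) also fell in this comparison, each with camera adjusted p = 0.0055 and adjusted p = 0.777 with an estimated correlation. The collagen gene Col1a1 differed by -0.94 ± 0.44, the matrix proteoglycan Bgn by -0.49 ± 0.30 and Mfap5 by -0.86 ± 0.38. Within number 1 the medians were 0.19 for matrix and 0.07 for fibroblast markers, and within number 2 they were -0.53 and -0.83. Without EC with AS-Tspan8 exosomes replicate 2 they were -0.02 (adjusted p = 0.863) and 0.01 (0.86) relative to all genes, and without EC with AS exosomes replicate 2 -0.05 (0.904) and -0.18 (0.282). Leukocyte markers had a median of -0.47 over 5 genes (0.0671), with -0.12 in number 1 and -0.84 in number 2. With the block, camera also called cell cycle genes lower (median -0.14, blocked adjusted p = 0.00132) and gave 0.037 each for interferon response genes (-0.12), glycolysis genes (0.24) and immediate early genes (0.18). With an estimated correlation the adjusted p = 0.793 for cell cycle and 0.777 for each of the other 3. Within numbers 1 and 2 the medians were -0.04 and -0.32 for cell cycle, -0.24 and -0.001 for interferon response, -0.09 and 0.50 for glycolysis and -0.02 and 0.29 for immediate early genes.

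Single genes did not separate EC with AS-Tspan8 from EC with AS exosomes. With limma 0 of 9025 features passed, 51 had an unadjusted p under 0.05 against 451 expected, the block gave 0 and 188, and groups did not overlap in 17.7% of features. Those of lowest p that were higher with AS-Tspan8 exosomes were Id1, an inhibitor of differentiation (0.69 ± 0.20), Cdhr1 (0.64 ± 0.19), Tut1 (0.45 ± 0.15) and Plekhn1 (0.49 ± 0.18). Those lower were the cardiac troponin gene Tnnt2 (-1.003 ± 0.28), the transcription factor Creb3l1 (-0.61 ± 0.19), Zcchc24 (-0.70 ± 0.22) and Wfdc21 (-0.70 ± 0.23). Adjusted p was 1 for each.

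Both exosome treatments were compared for likeness across genes. Log2 differences against untreated EC correlated at r = 0.623 (Spearman 0.615) over 9025 features, which are not independent replicates, and 72.5% had the same sign. Both share the untreated arrays, and simulated groups with no change against the same controls gave r = 0.504 and 66.8%. The covariance was 0.0268 against a simulated 0.0331, a difference of -0.0063. That simulation left out the pairing by replicate number. With the spread left by the replicate block, a simulation chosen after seeing the data gave r = 0.50, 66.7% and a covariance of 0.0177, a difference of 0.009, so the sign of the difference depended on the pairing. Both simulations include the shared controls, so that sharing is already in the simulated values. Pairs that shared no array, number 1 of one treatment against number 2 of the other, correlated at -0.046 and 0.072. Where no array was shared, the 2 treatments thus showed almost no likeness across genes.

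Transcripts carried by exosomes were sought in treated EC among genes not detected in untreated EC. For AS exosomes, 263 such features detected on both exosome arrays had a median log2 difference 0.0035 above that of 10423 features not detected in exosomes (camera with an estimated correlation, p = 0.715). For AS-Tspan8 exosomes the difference was 0.0114 for 436 against 10214 features (same test with an estimated correlation, p = 0.135). Of the 200 with the highest exosome signal the differences were 0.0001 (p = 0.913) and 0.0249 (p = 0.0914), again with an estimated correlation. None passed, and for AS-Tspan8 exosomes leaving out EC replicate 2 of that treatment gave 0.0229 (with an estimated correlation, p = 0.0354). Leaving out EC with AS exosomes replicate 2 turned the AS value to -0.01 (with an estimated correlation, p = 0.919).

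Exosomes of both lines were compared with the cells that made them. Transcripts of the cell division machinery fell in exosomes: 32 of 38 cell cycle genes were lower (33 adjusted over the list alone) and 0 higher, with a median of -2.26, or -1.44 relative to all genes. Of the 38, 30 were detected on no exosome array and 0 on all 4, so the median reflects the background of those arrays and is no measured size. Cdk1 was at least 5.36-fold lower (limma adjusted p = 0.0044), with signals of 6119 and 10060 in the 2 cell lines and 63.5 to 94.2 on the 4 exosome arrays. The ribonucleotide reductase subunit Rrm2 was at least 6.93-fold lower (0.00385), the replication helicase Mcm2 at least 3.09-fold lower (0.00379), and the replication clamp Pcna, detected on 3 of 4 exosome arrays, differed by -4.09 ± 0.60 (0.00709). The list passed camera (adjusted p = 3.24e-05; adjusted p = 0.913 with an estimated correlation; fry adjusted p = 0.000594), and without the AS cell array its median relative to all genes was -1.26 (camera adjusted p = 0.0544).

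Abundant cell transcripts were also lower in exosomes. The glycolytic enzyme Pgk1 read 26470 and 32050 in cells and 165.3 to 1159 in exosomes (-4.24 ± 0.76, adjusted p = 0.0116). The secreted protease Htra1 (7253 and 20550 in cells, 74.2 to 141.8 in exosomes, 0.0126) and the tetraspanin Tspan3 (6539 and 10620, 63.7 to 130.3, 0.0111) were detected on 1 of 4 exosome arrays. Calmodulin Calm2 differed by -4.22 ± 0.75 (0.0114), the nucleosome-binding protein Hmgn2 by -4.19 ± 0.49 (0.00457) and the prolyl isomerase Fkbp9, detected on 3 of 4, by -4.10 ± 0.65 (0.00862). These sizes depended on scaling. Pgk1, Calm2, Hmgn2 and Fkbp9 differed by -2.71, -3.18, -3.29 and -4.20 with median scaling and by -6.73, -7.20, -7.31 and -8.22 with no scaling. Apart from the cell cycle and the receptor genes described below, no list passed camera. Members of other lists were called lower, as were 4218 of all 9434 features. Of 17 tetraspanins 12 were lower and 1 higher (13 changed in all, adjusted over the list alone, camera adjusted p = 0.264). Tspan12 read 4271 and 7018 in cells and was detected on 1 of 4 exosome arrays, and Cd82 was at least 1.34-fold lower. Among 30 exosome biogenesis genes 13 were lower and 1 higher (14 adjusted over the list alone; camera adjusted p = 0.469), with the annexin Anxa2 detected on 2 and syntenin (Sdcbp) on 1 of 4 exosome arrays. Of 16 cholesterol synthesis genes 12 were lower and 1 higher (14 over the list alone; camera 0.199), with Msmo1 at least 2.67-fold and Dhcr7 at least 2.1-fold lower. Of 24 stress response genes 14 were lower (12 over the list alone; camera 0.304), with the chaperones Calr at -2.76 ± 0.38 and Hspa5 at -2.69 ± 0.32. The keratin Krt19 read 9554 and 20410 in cells and was detected on 1 exosome array, and the protease inhibitor Timp1 read 6207 and 12910 and was detected on 2. Of 60 cytosolic ribosomal protein genes 16 were lower and 6 higher (11 over the list alone; camera adjusted p = 0.421).

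A smaller set of transcripts was higher in exosomes than in the source cells. Clec7a, a receptor for fungal glucans, read 73.6 and 86.3 in cells and 311.3 to 732.6 in exosomes (limma adjusted p = 0.00379). The calcium channel subunit Cacng2 read 81.8 and 80.9 against 214.4 to 493.7 (0.00533), the ephrin Efnb3 67.5 and 77.6 against 153.4 to 473.8 (0.00942), Col1a2 62.9 and 70.0 against 198.6 to 371.9 (0.00411) and the neurofilament Nefl 62.7 and 60.6 against 168.4 to 516.2 (0.00561). Their sizes depended on scaling. With no scaling Clec7a was at least 8.37-fold higher, Cacng2 5.80-fold, Efnb3 4.86-fold, Col1a2 4.63-fold and Nefl 4.09-fold. With quantile scaling the same bounds came out at 35.0-fold, 24.8-fold, 20.9-fold, 19.9-fold and 17.9-fold. Background is removed before a bound is taken, so a bound can exceed the ratio of the signals. Quantile scaling gives cell and exosome arrays the same distribution, so its bounds hold on that scale only. The aldo-keto reductase Akr1c12 differed by 4.62 ± 0.75 (0.00903), Klhl14 by 4.41 ± 0.39 and the ribosomal protein Rps24 by 4.41 ± 0.39 (0.00379 each). Without scaling between arrays these 3 differed by -0.03, 0.70 (limma adjusted p = 0.141) and 0.76 (0.123), since their signals in cells and exosomes overlapped or lay close together. The Klhl14 probe read 275.3 and 428.8 in cells and 464.7 to 716.5 in exosomes. The Rps24 probe read nearly the same, 247.0 and 422.7 against 444.3 to 696.6, far below Rpl3 in cells (30330 and 27640). Whether these 2 probes report the genes they are named for was not tested. Olfactory and vomeronasal receptor genes, included as genes foreign to both tissues, were higher as a list, with 11 of 12 called (11 adjusted over the list alone). The median was 2.48, or 3.30 relative to all genes (camera adjusted p = 2.24e-08, adjusted p = 0.913 with an estimated correlation, fry adjusted p = 0.0168). Of the 12, 1 was detected on no exosome array and 7 on all 4. Probes were kept when detected on at least 2 of the 6 tumour arrays, 4 of them exosome arrays. The filter thus favours receptor genes that read high in exosomes, and the list's p-values are no independent support. Vom2r65 was at least 2.08-fold higher with no scaling and 9.37-fold with quantile scaling, and Vom2r59 differed by 3.29 ± 0.37, which without scaling was 0.08 (adjusted p = 0.852). Before normalization the median difference of the 12 probes was 0.29 (SD 0.62), at percentile 63.9 of probe lists matched on signal in the cells, and the 11900 probes detected on none of the 6 tumour arrays had a normalized median difference of 0.08.

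**Figure D4:**
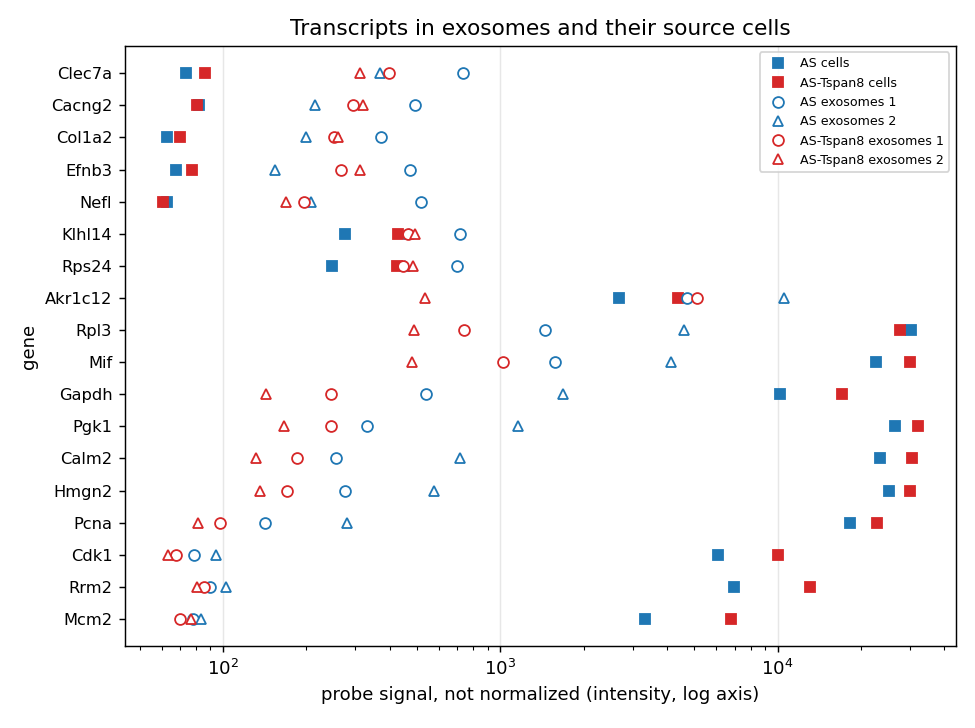
Signal before normalization of 18 named genes on the 2 cell arrays (filled squares) and the 4 exosome arrays (open symbols), on a log axis, AS in blue and AS-Tspan8 in red. Clec7a lies at 311.3 to 732.6 in exosomes and at 73.6 and 86.3 in cells, and Cdk1 at 63.5 to 94.2 in exosomes and at 6119 and 10060 in cells.

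In all, limma called 5738 of 9434 features (6741 named genes) between exosomes and cells, 1520 higher (26.5%, 737 named) and 4218 lower (3321 named), from 4 exosome and 2 cell arrays. Each line's cells had 1 array. The split depended on scaling: with median scaling 59.1% of 6723 calls were higher, and with no scaling 5.04% of 8585. Exosome arrays detect far fewer probes than cell arrays, but the cause of this dependence was not tested. The median of all genes was -0.82 with quantile, 0.39 with median and -3.63 with no scaling. In all 3 scalings 426 features were called higher and 1565 lower. Of the 1520 called higher, 152 were not detected on any exosome array. In signals before normalization, 374 features (93 named) were higher on all 4 exosome arrays than on both cell arrays and were detected on all 4, all called higher. In the other direction 8193 (86.8%) were lower on all 4 and detected in cells, which the lower total signal of exosome arrays favours. The count of calls was 643 without the AS-Tspan8 cell array (81.5% higher), 1986 without the AS cell array (54.8%), and 3601 and 3734 without AS-Tspan8 exosome replicate 1 and 2. Without the AS-Tspan8 or the AS cell array only 4174 and 4152 features met the detection filter, against 9434 in the main fit. Their counts and shares therefore reflect another set of features as well as the missing array. In simulated data 32 of 50 genes changed by 2 on the log2 scale were recovered in this comparison.

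The mRNA content of AS-Tspan8 exosomes was compared with that of AS exosomes. Housekeeping lists fell in AS-Tspan8 exosomes: cytosolic ribosomal proteins (55 of 60 lower, median -0.82, camera adjusted p = 3.43e-06), nuclear genes of oxidative phosphorylation (45 of 45 lower, -1.06, 9.98e-06), mitochondrial ribosomal proteins (54 of 56 lower, -0.82, 9.98e-06) and the proteasome (35 of 39 lower, -0.95, 9.98e-06). Olfactory and vomeronasal receptor genes were higher (10 of 12, median 0.58, 0.011). All 5 had an adjusted p = 0.855 with an estimated correlation, fry gave 0.835, and 0 members passed adjusted over the list alone. Among the 1487 features detected on all 4 exosome arrays, an analysis chosen after seeing the data, the first 4 lists again passed camera, with 46 of 50 ribosomal (adjusted p = 2.31e-11), 19 of 19 oxidative phosphorylation (5.23e-07), 7 of 7 mitochondrial ribosomal (0.0154) and 11 of 11 proteasome members lower (0.000692; adjusted p = 0.448 each with an estimated correlation). Glycolysis genes (10 of 10 lower, 0.000758), translation factors (11 of 12, 0.0188) and heat shock proteins (7 of 7, 0.0408) passed as well, again with 0.448 each at an estimated correlation, and the receptor genes did not (0.138). Only 10 lists had enough detected members to be tested. The 1487 features had a median of 0.26, and camera sets each list against them. A fall particular to the housekeeping lists is therefore not shown. The ribosomal protein Rpl3 differed by -1.14 ± 0.30 and Rpl35a by -0.88 ± 0.27. Ndufa10, a subunit of respiratory complex I, differed by -0.72 ± 0.18, and Ndufs1 of the same complex was not detected in AS-Tspan8 exosomes. The proteasome genes Psmg1 and Psmd1 were at least 1.24-fold and 1.43-fold lower.

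These shifts leaned on AS exosome replicate 2, the array closest to cells: 960 abundant cell transcripts kept a median of 3.98% of their cell signal there, against 1.16% in AS replicate 1 and 0.444% and 0.253% in the AS-Tspan8 exosomes. Without it the medians relative to all genes were -0.37 for cytosolic ribosomal proteins (camera adjusted p = 0.0132), -0.21 for mitochondrial ribosomal proteins (0.0418), -0.36 for the proteasome (0.0132) and -0.27 for oxidative phosphorylation (0.638), and 0.19 for the receptor genes (0.737). The receptor call was also lost without the AS cell array (0.079), the AS-Tspan8 cell array (0.0827) or AS-Tspan8 exosome replicate 2 (0.527 relative to all genes, 0.177).

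Telomerase RNA (Terc) gave the lowest p of any named gene between the exosome kinds. It read 224.7 and 206.0 in AS exosomes and 67.4 and 64.1 in AS-Tspan8 exosomes, where it was not detected, at least 2.27-fold lower (limma adjusted p = 0.687). Hnrnpu, a nuclear RNA-binding protein, read 393.1 and 446.5 against 112.9 and 109.7 (-1.79 ± 0.18, 0.687). The DNA-binding protein Fubp1 was at least 1.52-fold and the ligand Wnt4 at least 1.3-fold lower, or 1.28-fold and 1.09-fold with median scaling. After quantile normalization Abcf2 (1.17 ± 0.19), the transporter Slc35f5 (1.37 ± 0.25), the odorant receptor Or6c201 and the Golgi protein Tgoln2 were higher in AS-Tspan8 exosomes (adjusted p = 0.687 each), but their signals lay close together. Abcf2 read 116.6 and 123.9 in AS and 139.3 and 118.5 in AS-Tspan8 exosomes, Slc35f5 97.0 and 107.0 against 112.3 and 108.5, Or6c201 100.4 and 96.5 against 98.0 and 105.3, and Tgoln2 104.4 and 90.4 against 113.4 and 107.5. With no scaling Abcf2 differed by 0.33 and Slc35f5 by 0.32. Of 30 exosome biogenesis genes 23 were lower (median -0.26, camera adjusted p = 0.406), and of 17 tetraspanins 9 (-0.04, 0.881).

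By limma 0 of 9434 features passed between AS-Tspan8 and AS exosomes, while 661 had an unadjusted p under 0.05 against 472 expected; the block gave 0 and 259. Median scaling called 304 (261 higher), a filter for detection on every array 9, and 1 fit over all 12 arrays 474 (242 higher). Without the AS cell array 39 of 4152 features were called and without the AS-Tspan8 cell array 45 of 4174. Fewer features met the detection filter in these fits than the 9434 of the main fit. The counts of 39 and 45 therefore reflect another set of features as well as the missing array. The median of all genes was -0.08 with quantile, 0.69 with median and -0.25 with no scaling. In simulated data 0 of 50 genes changed by 3 on the log2 scale were recovered, so a count of 0 does not show that the exosomes were alike.

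Whether the step from cell to exosome differed between lines was tested as an interaction. By camera 12 lists passed, 11 of them lower in the AS-Tspan8 line, and 4 of them also among the 1487 features detected on all 4 exosome arrays, an analysis chosen after seeing the data. Relative levels fell for proteasome genes (36 of 39 lower, median -0.97, adjusted p = 0.000464; 0.00581 with detected members), glycolysis and hypoxia genes (22 of 25, -0.83, 0.0265; 0.000841), cytosolic ribosomal proteins (48 of 60, -0.44, 0.0183; 2.35e-07) and oxidative phosphorylation (37 of 45, -0.90, 0.0265; 0.000827). Translation factors passed only among the detected features (9 of 12 lower, 0.0402; 0.489 with an estimated correlation). All 12 had an adjusted p = 0.795 with an estimated correlation, these 4 with detected members 0.489, and fry gave 0.488 to 0.847. With no scaling between arrays the camera test turned to the other direction for each of these 4 lists, although their medians stayed below that of all genes. The 1487 features, against which the detected members were tested, had a median of 0.34.

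The other lists of the interaction rested on few transcripts seen in exosomes. Cholesterol synthesis (15 of 16 lower, median -0.78, camera adjusted p = 0.000464) had 2 members detected on all 4 exosome arrays, NF-kB targets (13 of 14, -0.88, 0.00169; 1 called adjusted over the list alone) 1, immediate early genes (15 of 16, -0.765, 0.00169) 1, matrix genes (12 of 15, -0.37, 0.00119) 1 and the unfolded protein and ATF4 response (21 of 24, -0.49, 0.0265) 3, too few to test. Interferon response (23 of 26, -0.66, 0.000464) had 6 detected members (adjusted p = 0.061), mitochondrial ribosomal proteins (52 of 56, -0.62, 0.0116) 7 (0.203) and the receptor genes, higher (10 of 12, 0.70, 0.00173), 7 (0.1). The adhesion receptors Vcam1 and Selp, the interferon-induced GTPase Gbp2, the sterol enzymes Sc5d and Fdft1 and the matrix genes Col15a1 and Fn1 were detected on no exosome array, so no size is given for them. In cells Vcam1 read 98.3 in AS and 3229 in AS-Tspan8 and Fn1 487.7 and 3660. Without AS exosome replicate 1 the matrix list lost its call (-0.525, adjusted p = 0.283).

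Leaving out 1 other array removed further calls. Without AS exosome replicate 2 the medians relative to all genes, none called, were -0.09 for glycolysis, -0.13 for the unfolded protein and ATF4 response, -0.10 for cytosolic and -0.06 for mitochondrial ribosomal proteins, -0.10 for oxidative phosphorylation and 0.32 for the receptor genes. The first 5 also lost their call without AS-Tspan8 exosome replicate 2, at -0.37, -0.50, -0.02, -0.30 and -0.29.

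Single genes did not pass the interaction test: limma called 0 of 9434, 199 had an unadjusted p under 0.05 against 472 expected, and the block gave 0 and 51. Among the genes named by rule, those of lowest p were Terc, which was not detected in AS-Tspan8 exosomes and has no size here, the galectin Lgals3 (-2.07 ± 0.37), Smap2 (-1.89 ± 0.38, detected on 3 of 4 exosome arrays) and Hnrnpu (-1.49 ± 0.31), and in the other direction Slc35f5 (1.58 ± 0.43, also on 3), Map3k12 (1.28 ± 0.36), Tfb1m (1.02 ± 0.30) and Hebp2 (1.11 ± 0.33), all with adjusted p = 0.989. Median scaling called 218 (90.4% higher), 1 fit over all 12 arrays 15, and no scaling 4548 (1.41% higher). The median of all genes was -0.12, 0.59 and -1.25 with quantile, median and no scaling, and without scaling the last 4 genes were at -0.36, -0.45, -0.18 and -0.57.

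AS-Tspan8 cells were set beside AS cells with 1 array each, which gives values with no replicate check and no test. Reg1a, a pancreatic secreted lectin, read 107.1 in AS and 4622 in AS-Tspan8 cells, the tight-junction protein Cldn2 112.3 and 4790, the alarmin Il33 105.5 and 4027, aromatase (Cyp19a1) 93.7 and 3457, complement factor I (Cfi) 296.6 and 10650, and choline dehydrogenase (Chdh) 448.8 and 8610. The retinaldehyde dehydrogenase Aldh1a1 read 1669 and 15760 and the glutathione transferase Gstp1 9391 and 30090. In the other direction, the growth factor Igf2 read 32530 and 6536, the transcription factor Gata2 3967 and 436.9, the NADPH oxidase subunit Cyba 2026 and 103.4 (at least 7.37-fold lower), argininosuccinate synthase (Ass1) 1383 and 82.4 (at least 5.35-fold) and Gstk1 1255 and 91.1 (at least 4.97-fold). Rplp0, Tuba1b and Rpl3, near the top of the signal range, differed by -2.63, -2.30 and -2.24 when normalized with the exosome arrays but by -0.41, -0.39 and -0.27 with the cell arrays alone.

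Between the cell lines, 146 of 9690 features were higher in AS-Tspan8 cells and 104 lower by at least 1 on the log2 scale, and with the cell arrays normalized alone 486 and 424 were. Of these, 114 and 81 were shared, and 0 had opposite signs. List medians above 0, beyond the central 95% of random lists of like expression, were found for cholesterol synthesis (0.35), extracellular matrix (0.33), matrix proteases and inhibitors (0.325), NF-kB targets (0.30), immediate early genes (0.28), angiogenesis (0.24), chemokines (0.24), the unfolded protein and ATF4 response (0.20) and interferon response (0.19), and for integrins (0.32), leukocyte markers (0.28) and glycolysis (0.14). With the cell arrays normalized alone these medians were, in the same order, 0.47, 0.735, 0.44, 0.64, 0.73, 0.65, 0.48, 0.24, 0.38, 0.545, 0.64 and 0.17. Medians below the central 95% were found for oxidative phosphorylation (-0.23), cytosolic ribosomal proteins (-0.16) and mitochondrial ribosomal proteins (-0.15). Random lists draw genes independently, so their ranges are too narrow for lists whose members vary together. With 1 array per line, a median beyond the range does not show a difference between the lines. Of the genes that differed between cells and were detected on all 4 exosome arrays, 31 of 36 higher and 24 of 29 lower in AS-Tspan8 cells were lower in AS-Tspan8 exosomes. These genes were picked by cell differences normalized with the exosome arrays. That scaling enlarged differences near the top of the signal range, as given above for Rplp0, Tuba1b and Rpl3. No such count was made with the cell arrays alone, so whether direction in exosomes followed that in cells is not decided. Of all 1218 features detected on those arrays and in cells 44.6% were lower, and with no scaling 90.4%.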

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

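Tests of the scaling of the cholesterol list, of its shared direction by replicate number and of the split housekeeping lists were chosen after the results were seen. The results here are list shifts in which 2 treatments or 2 cell lines differed by camera at a preset correlation. With an estimated correlation the adjusted p = 0.777 for each EC list and 0.795 for each interaction list.

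Cholesterol synthesis genes differed by a median of -0.383 between EC with AS-Tspan8 and EC with AS exosomes, with all 16 members lower. The tables argue against the scaling between arrays as the cause: relative to all genes the median was -0.386 to -0.399 with quantile, median and no scaling, although a constant factor per array cancels in this value and only the shape of the scaling was tested. A single replicate number stays open, since the median was -0.12 in number 1 with 11 of 16 members lower and -0.725 in number 2 with 16 of 16. Variation between samples of one treatment also stays open: the untreated arrays differed by -0.577 with 16 of 16 members the same way, more than the treatment difference, but replicates 1 and 2 differed the same way with AS (-1.397) and AS-Tspan8 exosomes (-0.644), so the shared part cancels within pairs, and the blocked adjusted p was 9.71e-10. An effect of Tspan8 in the donor cells remains open and untested.

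Proteasome, ribosomal and oxidative phosphorylation lists were lower in AS-Tspan8 exosomes than in AS exosomes. Dependence on AS exosome replicate 2 stays open: without it the medians relative to all genes were -0.214 to -0.366, smaller but below 0. A lower share of all abundant cell mRNA would move matched lists alike, and 3 of 4 lists lay below the central 95% of lists matched on level in the cells, with percentiles from 0.08 to 31.6. For the mitochondrial ribosomal, oxidative phosphorylation and proteasome lists the highest percentile was 1.28, and the cytosolic ribosomal list lay at percentile 31.6. The lists were split after these percentiles were seen. Random lists draw genes independently, whereas members of the 4 lists had estimated correlations of 0.392 to 0.65. That explanation therefore stays open. The difference between lines named by the design remains an open, untested explanation.

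In the same EC comparison extracellular matrix genes differed by -0.173 and fibroblast markers by -0.316. In the test of the cell-to-exosome step between lines, where of these lists only glycolysis, cytosolic ribosomal, oxidative phosphorylation and proteasome also passed among transcripts detected on all 4 exosome arrays (adjusted p = 0.489 each with an estimated correlation), the medians were -0.875 for NF-kB targets, -0.658 for interferon response, -0.834 for glycolysis, -0.782 for cholesterol synthesis, -0.492 for the unfolded protein and ATF4 response, -0.765 for immediate early genes and -0.367 for extracellular matrix. They were -0.444 for cytosolic and -0.617 for mitochondrial ribosomal proteins, -0.904 for oxidative phosphorylation, -0.967 for the proteasome and 0.703 for olfactory and vomeronasal receptors.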

How the results depend on the processing

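Over all settings, values of named genes kept their direction and side of the threshold 1714 times, gained a call 40 times, lost one 15 times and turned sign 6 times. Only exosomes against cells had gene calls in the main fit, so elsewhere a kept side means that a gene stayed uncalled. Of 64 values of genes that differed between the cell lines, which have no test, 0 turned sign, but sizes moved. With median scaling Gstp1 went from 3.51 to 0.79 and Cldn2 from 2.93 to 5.42. List calls were kept 220 times, lost 90 times and turned 14 times. The settings chosen after seeing the data were no scaling between arrays, the crossed pairing, the cell arrays alone, and, for lists, the replicate block and left-out arrays. The cause of the changes was not tested, except that a left-out array leaves fewer samples and a stricter detection filter fewer genes. Leaving out the AS or AS-Tspan8 cell array also cut the tumour features tested from 9434 to 4152 or 4174. When an arm keeps 1 array, that array is assumed to vary like the other groups. A slide block was not run because the files name no slide. Low signal over background limits the exosome arrays, of which 9.342% to 16% of probes were detected.

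Counts of lists called were 1 for AS exosomes against untreated EC (A), 6 for AS-Tspan8 exosomes against untreated EC (B), 3 for the EC treatments against each other (C), 5 for the exosome kinds (D), 2 for exosomes against cells (E) and 12 for the interaction (F). With an estimated correlation all were 0, and with fry 0 except 17 for exosomes against cells. The replicate block gave 4 for A and 7 for C, changed the list calls named beside the results, and changed no other call of a gene count in EC. No background correction gave 9 and median scaling 7 for C, and median scaling 14 for exosomes against cells. No scaling gave 4, 5, 7 and 7 for A, C, E and F. Leaving out single arrays gave, from A to F, 2 to 6, 0 to 9, 3 to 6, 3 to 9, 2 to 9 and 6 to 14.

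Calls between exosome kinds (0) were 304 with median scaling, 9 with detection on every array, 474 with 1 fit over 12 arrays and 0 to 45 without single arrays. The crossed pairing gave 0 calls, with 1363 features at an unadjusted p under 0.05. Calls between exosomes and cells (5738) were 765 with detection on every array, 4745 with the replicate block and 643 to 7140 without single arrays. The share higher (26.5%) was 59.1% with median scaling, 39.3% without a filter, 71.0% with detection on every array, 23.3% with a trend and robust estimation, 28.3% with the replicate block, 5.04% with no scaling and 25.3% to 81.5% without single arrays. Interaction calls (0) were 218 with median scaling, 15 with 1 fit and 4548 with no scaling. Between the cell lines 146 and 104 became 80 and 59 without background correction, 449 and 540 with median scaling and 486 and 424 with the cell arrays alone. The correlation of the treatments was 0.648 without background correction. Exosome transcripts in treated EC differed by -0.0017 for AS exosomes at the stricter absence limit, by -0.01 without EC with AS exosomes replicate 2 and 0.0075 without untreated replicate 1, and by 0.0229 for AS-Tspan8 exosomes without EC replicate 2 and 0.0083 without EC replicate 1 of that treatment.

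Values that turned were, for AS-Tspan8 exosomes against untreated EC, cell cycle at 0.01 without untreated replicate 2 and -0.018 without treated replicate 1, and without treated replicate 2 glycolysis at -0.173, matrix at -0.055 and fibroblast markers at 0.045. For EC treatments against each other they were cholesterol synthesis at 0.228 and matrix at -0.053 without EC with AS exosomes replicate 2, and fibroblast markers at 0.01 without EC with AS-Tspan8 exosomes replicate 2. Without other arrays the same lists reached, for B, cell cycle -0.696 (treated replicate 2), glycolysis 1.045, matrix -0.448 and fibroblast markers -0.658 (treated replicate 1) and matrix -0.023 (untreated replicate 2). For C they reached cholesterol synthesis -1.114 (AS exosomes replicate 1), matrix -0.421 and fibroblast markers -0.732 (AS-Tspan8 exosomes replicate 1). Where a negative median is listed for a falling list, the camera test had turned, not the median. With no scaling Akr1c12 was -0.029 in exosomes against cells, and in the interaction Slc35f5 was -0.361, Map3k12 -0.451, Tfb1m -0.183 and Hebp2 -0.567. Camera likewise turned for glycolysis (-0.862), cytosolic (-0.863) and mitochondrial (-0.436) ribosomal proteins, oxidative phosphorylation (-1.033) and the proteasome (-0.926), and for oxidative phosphorylation (-0.096) without AS exosomes replicate 2, against -1.487 without replicate 1. The fitted value of Sc5d, which was detected on no exosome array and has no measured size, turned to 0.444 with median scaling.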

Other observations

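The tests of list detection in exosomes, of exosome-dominant probes and of cell type markers in EC were chosen after the data were seen.

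Exosomes held the transcripts of the cytosolic ribosome far more often than other cell transcripts. Of 8705 genes detected in both cell lines, 1175 (13.5%) were detected on all 4 exosome arrays, and of 60 cytosolic ribosomal protein genes 50 (83.3%) were (Fisher's exact test, adjusted p = 5.29e-33 over the lists), where lists matched on level in the cells gave 27 to 39. Nuclear oxidative phosphorylation genes (19 of 44, 1.34e-05), glycolysis genes (10 of 25, 0.00644) and translation factors (12 of 35, 0.00761) were also detected more often than all genes by the exact test, but within the matched ranges of 16 to 27, 5 to 12 and 6 to 14. Of 38 cell cycle genes 0 were detected (0.0302), where matched lists gave 3 to 11, and of 16 tetraspanin genes 0 (0.355), where matched lists gave 1 to 6. The exosome biogenesis genes gave 2 of 29 (0.798). The cell arrays carry no starvation time, so these cells may have differed in state from those that shed the exosomes.

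Transcripts with strong signals in exosomes included the aldo-keto reductase Akr1c12 (4718 and 10530 in AS, 5127 and 535.2 in AS-Tspan8 exosomes), the ribosomal protein Rplp0 (3209 and 12060 in AS, 2276 and 1543 in AS-Tspan8 exosomes) and the ferritin heavy chain Fth1 (2631 and 10230, 4153 and 1502). In all, 1495 probes (6.64%) were detected on all 4 exosome arrays, 857 named and 638 unnamed, and the 2011 probes detected on both AS and 1860 on both AS-Tspan8 exosome arrays would share 166.1 by chance. Of the 1495, 269 were not detected in either cell line, 61 named and 208 unnamed.

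Samples labelled EC showed 3 of 18 endothelial markers detected on all 6 arrays, where random lists of named genes gave 4 to 12, so the low number is not one that any gene list would give. Fibroblast markers gave 12 of 14, where random lists gave 3 to 10. This pattern is consistent with cells of fibroblast type in the cultures, as a hypothesis from the data: Dcn read 22430 to 26660, Col1a2 14680 to 27370 and Lum 9683 to 15350, although Col1a1 read 118.7 to 310.2 and Mfap5 81.7 to 168.0. Cells other than endothelium that express these genes are not excluded, and of 11 smooth muscle markers 4 were detected. No biological explanation, such as loss of endothelial markers in culture or after starvation, was tested.

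A hypothesis that RNA of the added exosomes remained in EC samples was tested with 23 unnamed probes that read above 1000 on every exosome array and on average at least 4 above the cells on the log2 scale. The strongest read 27130 to 31730 in exosomes, 1307 and 2200 in tumour cells and 659.6 and 978.5 in untreated EC. These probes exceeded the range of matched random lists in 1 of 4 treated EC arrays, AS-Tspan8 replicate 1, with a median rise of 0.478 over the untreated array of the same number and 23 of 23 higher. The other medians were 0.009, 0.021 and 0.065, within the random ranges. Over the 23 probes the rise in that array correlated with their mean exosome signal at Spearman 0.263 and Pearson 0.402. Random lists draw probes independently, whereas these 23 may not be independent of each other. Carried-over RNA may account for the rise in that array, but a rise in 1 array only does not decide it.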
